A study of Mus musculus with 4 samples.

How the data were processed

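RNA was measured by poly(A)-selected, paired-end Illumina sequencing of thyroids from NOD.H-2h4 mice, a strain prone to autoimmune thyroiditis. The mice had been injected 3 times a week for 2 weeks with either an antibody against PD-L1 or an isotype control IgG. The titles name a mouse and a replicate number for each library, with 2 libraries per group. The labels also give a batch field with a different antibody clone string for each of the 4 libraries, so it could not enter any model.

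The deposited values are expected counts per gene symbol, not normalized, in 1 table of 16218 genes and 4 value columns. Per the submitters' processing notes, BWA and the mm10 build were used, with no role or version stated. The counting program, annotation, strand setting and gene filter are not given in the sources used here. The deposited counts were whole except in 3328 genes (20.5%), which had a count ending in 0.5 in at least 1 library. Exons of 37.1% of those genes overlapped an exon of another gene in GENCODE release 21 for mouse, against 34.1% of the other genes, so overlapping annotation did not separate them. Each listed gene reached a count of at least 100 in at least 1 library, which shows that low genes had been removed before deposit. No cell was listed at 0, and 13 cells in 12 genes were blank and were read as 0. Immunoglobulin constant genes, T cell receptor constant genes, mitochondrially encoded genes and Cd80 were not among the listed symbols. Gene coordinates came from GENCODE on GRCm38, the assembly also called mm10, in which 15871 of the listed symbols were found once.

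Expected counts were rounded to whole numbers. As a check for one library deposited under 2 names, the counts of the 2 libraries of each group were compared with sampling noise (chi-square per degree of freedom 321 for IgG and 1056 for anti-PD-L1), which says nothing of how animals vary. Library totals were 79663374.5 and 77492328 counts in the IgG group and 75591923 and 77685257 in the anti-PD-L1 group. At that depth 3 counts correspond to 0.0377 to 0.0397 CPM, a floor that covers counting error only. Tests used edgeR 4.0.16 in R 4.3.3, with filterByExpr (16217 genes kept), TMM factors, robust dispersion estimation and the quasi-likelihood F test on group alone, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The residual degrees of freedom were 2, the median prior degrees of freedom 2.42 and the median biological coefficient of variation 24.4%. CPM values are TMM-normalized. Log2 fold changes are anti-PD-L1 minus IgG, and each standard error was taken as the absolute log2 fold change divided by the square root of F. An exact two-sided permutation test of a single value between 2 and 2 libraries cannot go below p = 0.333, so single values are given with their fitted errors. The edgeR p-values rest on the spread between these samples, estimated in part across genes.

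A set of 42 gene lists was fixed before the data were examined, covering pathways (autophagy, lysosome, apoptosis, interferon responses, antigen presentation and others), thyroid function, immune cell types and tissues next to the thyroid. They were tested with camera from limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the 42 lists, then again with an estimated correlation and with fry. Camera p-values with the preset correlation treat a list's genes as nearly independent and do not measure the spread between animals. For each list, members were also counted as adjusted over the list alone. A list's deviation in a library is the mean, over its genes, of log2 CPM (prior count 2) minus the gene's mean over the 4 libraries.

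The rule for named genes, fixed at the same time, took up to 12 genes per direction with the largest fold change among those past the threshold, with a mean of at least 1 CPM, groups that did not overlap and no provisional symbol. Where fewer than 5 passed, genes of smallest p were added up to 5 and said not to pass. The rule also took Cd274, Pdcd1, Pdcd1lg2 and Cd80, the 4 members of smallest p of each list past the threshold and of the autophagy, lysosome, apoptosis, thyroid and interferon gamma lists, up to 2 members of each other list, and the gene of largest count in each library. Other genes are said to have been chosen after their values were seen.

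Alternatives were RLE, upper-quartile and plain library-size scaling, no filter, a stricter filter (at least 1 CPM in at least 2 libraries and a mean count of at least 20), DESeq2 1.42.0, limma voom, the replicate number as a block, each library left out in turn, neighbouring-tissue genes left out, an adjusted p under 0.10 and a minimum absolute log2 fold change of 1. Leaving out genes with a blank cell, DESeq2 with each library left out and DESeq2 with the block were added after seeing the data. The steps were tested on simulated data for this comparison, with 200 of 16217 genes changed at the estimated spread. edgeR recovered 2 of 67 genes changed 2-fold, 46 of 67 changed 4-fold and 62 of 66 changed 8-fold, and called 25 unchanged genes. DESeq2 recovered 14, 59 and 64 of those genes and called 104 unchanged genes, and voom recovered 0, 31 and 60 and called 16 unchanged genes. In a second simulation, camera found a list of 30 genes raised 4-fold and called 0 of the unchanged lists. The camera adjusted p of the raised list was 6.94e-112 under the preset correlation and 0.0298 under an estimated correlation. That simulation held 20 lists with genes drawn independently, whereas estimated correlations in the 42 fixed lists reached 0.98. It therefore does not show how often camera misses or falsely calls the fixed lists. Figures were drawn with matplotlib 3.10.9.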

Results

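The data comprised 4 thyroid RNA-seq libraries from NOD.H-2h4 mice, 2 from mice given isotype control IgG and 2 from mice given an antibody that blocks PD-L1, the ligand of the inhibitory T cell receptor PD-1. Total counts per library ranged from 75591923 to 79663374.5. The gene with the largest count in each library was Tg, which encodes thyroglobulin, the precursor of thyroid hormone. It took 15.3% and 14.6% of all counts in the IgG libraries, 16.9% in anti-PD-L1 replicate 2 and 4.34% in anti-PD-L1 replicate 1.

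Log2 CPM correlated across genes, which are not independent replicates, with r = 0.967 between the IgG libraries and r = 0.938 between the anti-PD-L1 libraries, while IgG replicate 2 and anti-PD-L1 replicate 1 had r = 0.963. The leading principal component carried 54.0% of the variance and placed IgG replicate 1 at −52.3, IgG replicate 2 at −14.8, anti-PD-L1 replicate 1 at 2.34 and anti-PD-L1 replicate 2 at 64.8. The next component, with 31.4%, set anti-PD-L1 replicate 1 (53.3) apart from the other 3 libraries (−27.1 to −1.99). Anti-PD-L1 replicate 1 also had 1.40 CPM of Xist, the RNA expressed from an inactive X chromosome, against 67.7 to 72.7 CPM in the other libraries, and 62.6 CPM of the Y-linked gene Ddx3y against 0.350 to 0.790 CPM. These 2 genes were chosen after their values were seen.

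The aim of the series was to find thyroid genes and pathways that differ after PD-L1 is blocked. Genes of the interferon response and of antigen presentation, and marker genes of T cells, cytotoxic cells and macrophages, had mostly higher values in both anti-PD-L1 libraries than in both IgG libraries, with list medians between 1.35 and 2.75 on the log2 scale. Genes of the autophagy machinery showed no such difference, with a list median of −0.00095. No single gene passed the threshold in the main test. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower, the smallest adjusted p being 0.0635, while 982 genes had an unadjusted p under 0.05 (804 higher and 178 lower). limma voom also called 0, with 1047 genes at an unadjusted p under 0.05, and DESeq2 called 475 higher and 53 lower. In the simulation described above DESeq2 also called 104 unchanged genes, so false calls may be among these. Of the 528 genes that DESeq2 called, 527 had groups that did not overlap, which the call itself favours. In all, 16.5% of genes had both anti-PD-L1 libraries above both IgG libraries and 13.1% had both below, where chance gives 16.7% in each direction. With 2 libraries per group no exact permutation p can be below 0.333. Genes of other epithelia, chosen after their values were seen, varied by library. Summed CPM of 9 squamous genes was 13637 and 3481 in the IgG libraries and 6276 and 93.1 in the anti-PD-L1 libraries, and that of 12 mucosal gland genes was 6392 and 41126 against 69799 and 18090.

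Cd274, which encodes PD-L1 and lies on chromosome 19 from 29367455 to 29388095 of GRCm38, had 23.1 and 10.0 CPM in the IgG libraries and 34.8 and 26.6 CPM in the anti-PD-L1 libraries. Its log2 fold change of 0.89 ± 0.45 (SE, n = 2 per group) did not pass (edgeR adjusted p = 1). The antibody binds the protein, so this value checks no label. Pdcd1, the gene of PD-1 on chromosome 1 from 94038305 to 94052553, had 0.613 and 1.56 CPM against 13.8 and 12.5 CPM, a log2 fold change of 3.60 ± 0.52 (edgeR adjusted p = 0.2 over all genes). Pdcd1lg2, the gene of PD-L2, had 0.10 and 0.83 CPM against 2.60 and 1.88 CPM (edgeR adjusted p = 0.927).

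**Figure D1:**
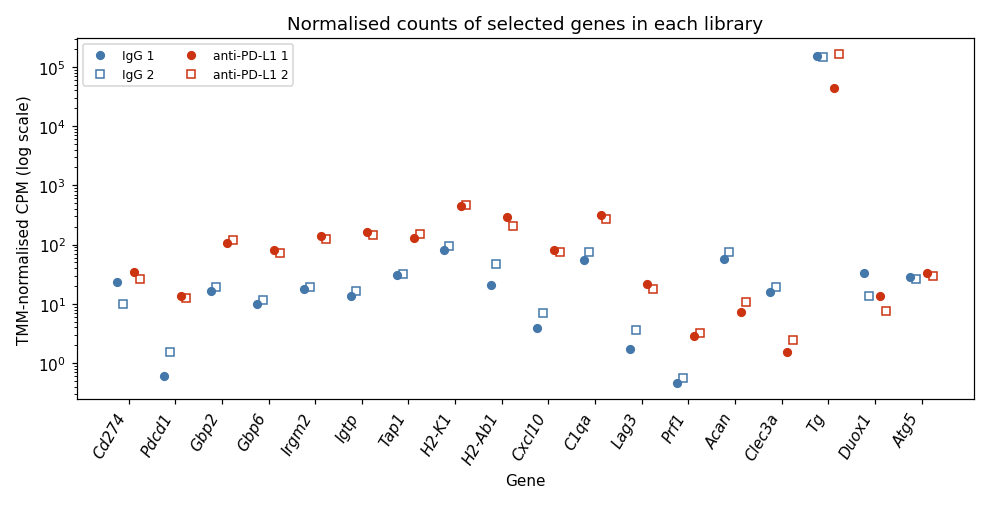
TMM-normalised CPM on a log axis for 18 genes in each of the 4 libraries, blue for IgG and red for anti-PD-L1, filled circles for replicate 1 and open squares for replicate 2. Gbp2 lies at 16.6 and 19.3 CPM in the IgG libraries and at 107 and 117 CPM in the anti-PD-L1 libraries, while Atg5 lies between 26.7 and 33.6 CPM in all 4.

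None of the genes of smallest p in either direction passed over all genes with edgeR, provisional symbols set aside, while DESeq2 called each of the 10 named here (DESeq2 adjusted p from 3.34e-39 for Irgm2 to 1.26e-06 for Hapln1). The 5 with higher values were Gbp6, Irgm2, Igtp, Gbp2 and Ifi205, 4 interferon-inducible GTPases and, in Ifi205, an interferon-inducible gene of the Ifi200 family, each with an edgeR adjusted p of 0.0833. Their log2 fold changes were 2.84 ± 0.17 for Gbp6, 2.85 ± 0.17 for Irgm2, 3.35 ± 0.21 for Igtp, 2.32 ± 0.15 for Ifi205 and 2.65 ± 0.17 for Gbp2. Igtp, on chromosome 11 from 58199556 to 58207591, overlaps Irgm2 (58199618 to 58222782) on the same strand, and the Gbp and Irg families hold close paralogs, so the split of reads among these genes is uncertain. The 5 with lower values were Acan, Clec3a, Susd5, Ada and Hapln1. Acan, the gene of the cartilage proteoglycan aggrecan on chromosome 7 from 79053483 to 79115099, had 56.3 and 75.1 CPM in the IgG libraries against 7.35 and 10.6 CPM (log2 fold change −2.87 ± 0.28, edgeR adjusted p = 0.162). Clec3a had 15.9 and 19.1 CPM against 1.54 and 2.49 CPM (edgeR adjusted p = 0.162), and Ada, which encodes adenosine deaminase, had 34.9 and 22.1 CPM against 6.42 and 4.64 CPM (edgeR adjusted p = 0.2). Susd5 and Hapln1 had log2 fold changes of −1.85 ± 0.24 and −2.18 ± 0.31.

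Of the 42 fixed lists, camera with the preset correlation called 19 higher and 2 lower in anti-PD-L1. With an estimated correlation 0 lists were called, the smallest adjusted p being 0.184. The pro-apoptotic list had an estimated correlation of −0.00328, below the preset 0.01, yet its unadjusted camera p was 0.0755 against 0.00273. The loss of calls therefore cannot be put down to correlation between genes alone. The fry test, which asks whether a list's genes move on balance one way, called 2 lists. They were the MHC class I list (fry adjusted p = 0.0258) and the interferon gamma list (fry adjusted p = 0.0453). These lists share Tap1, Psmb8, Psmb9 and Nlrc5, so they are not independent calls. The number of calls did not by itself mark the treatment. A split of the libraries that set IgG replicate 2 and anti-PD-L1 replicate 1 against the other 2 called 20 lists, though 1 of those had an absolute median above 1, against 10 in the treatment comparison.

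The interferon gamma list had the smallest camera p. Of its 33 genes, 31 had both anti-PD-L1 libraries above both IgG libraries, 25 were higher adjusted over the list alone with edgeR, and over all genes edgeR called 0 and DESeq2 24. The median log2 fold change was 2.39, a 5.24-fold higher level (camera adjusted p = 2.66e-75, and adjusted p = 0.184 with an estimated correlation). Igtp had 13.6 and 16.8 CPM in the IgG libraries and 166 and 144 CPM in the anti-PD-L1 libraries. The type I interferon list had 35 genes with a median of 1.57, and 28 were higher adjusted over the list alone (camera adjusted p = 1.65e-52, and adjusted p = 0.264 with an estimated correlation). Among these, Zbp1, a sensor of Z-form nucleic acids, had 3.36 and 4.44 CPM against 22.05 and 22.01 CPM, and Trim30a, Stat2 and Usp18 had log2 fold changes of 2.71 ± 0.23, 1.66 ± 0.20 and 1.59 ± 0.20. The count adjusted over this list alone was lower with any library left out, most so without anti-PD-L1 replicate 2. The list's median ranged from 1.27 to 1.86 with each library left out in turn.

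Antigen presentation genes had higher values for both MHC classes. In the MHC class I list, 18 of 21 genes were higher adjusted over the list alone, with a median log2 fold change of 1.87 (camera adjusted p = 1.25e-47, and adjusted p = 0.184 with an estimated correlation). Tap1, a subunit of the peptide transporter, had 30.6 and 32.3 CPM against 128 and 148 CPM. Psmb8, a catalytic subunit of the immunoproteasome, had 44.5 and 53.2 CPM against 220 and 204 CPM. H2-K1, a class I heavy chain, had 81.1 and 96.5 CPM against 454 and 464 CPM, and H2-T22 had a log2 fold change of 1.55 ± 0.15. H2 class I genes are near-identical copies, so their separate levels are uncertain. The count over the class I list alone was lower when either IgG library was left out. The class I median ranged from 1.69 to 1.92 with each library left out in turn. The MHC class II list had 12 genes with a median of 2.50, and 11 were higher adjusted over the list alone (camera adjusted p = 4.55e-29, and adjusted p = 0.264 with an estimated correlation). H2-Ab1 had 20.6 and 47.3 CPM against 298 and 208 CPM, and Ctss, which encodes cathepsin S, had 30.7 and 49.8 CPM against 274 and 208 CPM. H2-DMa and Ifi30 had log2 fold changes of 2.49 ± 0.45 and 1.49 ± 0.27. Fewer class II genes passed over the list alone when either anti-PD-L1 library was left out. The class II median ranged from 1.90 to 3.27 with each library left out in turn.

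Markers of T cells and cytotoxic cells were higher as lists. All 14 genes of the NK and cytotoxic list were higher adjusted over the list alone, with a median log2 fold change of 2.75 (camera adjusted p = 5.36e-40, and adjusted p = 0.264 with an estimated correlation). Prf1, the gene of perforin, had 0.463 and 0.565 CPM against 2.93 and 3.17 CPM, and Gzma, the gene of granzyme A, had 0.838 and 1.05 CPM against 5.08 and 7.69 CPM. The lectin receptor genes Klrk1 and Klrd1 had log2 fold changes of 2.75 ± 0.31 and 2.54 ± 0.32. In the T cell list 15 of 21 genes were higher adjusted over the list alone, with a median of 1.75 (camera adjusted p = 1.52e-31, and adjusted p = 0.264 with an estimated correlation). Cd3g had 2.43 and 4.08 CPM against 18.8 and 15.3 CPM, Zap70 4.03 and 4.56 CPM against 13.6 and 12.1 CPM, and Foxp3, the regulatory T cell factor, 1.48 and 2.01 CPM against 5.50 and 5.96 CPM. The T cell count adjusted over the list alone was lower when either anti-PD-L1 library was left out. The T cell median ranged from 1.29 to 2.42 with each library left out in turn.

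The list of co-inhibitory and co-stimulatory genes had 15 of 25 members higher adjusted over the list alone and a median of 1.58 (camera adjusted p = 1.82e-27, and adjusted p = 0.264 with an estimated correlation). Lag3 had 1.75 and 3.66 CPM against 21.7 and 17.7 CPM, Havcr2, the gene of TIM-3, had 3.95 and 4.58 CPM against 13.5 and 13.6 CPM, and Lgals9 18.7 and 19.3 CPM against 43.5 and 47.5 CPM. The count for this list was lower when either anti-PD-L1 library was left out, while its median ranged from 1.19 to 1.78 with each library left out in turn. Chemokine genes had 14 of 24 members higher adjusted over the list alone, with a median of 1.57 (camera adjusted p = 1.99e-22, and adjusted p = 0.264 with an estimated correlation). Cxcl10, a ligand of the receptor CXCR3, had 3.877 and 6.999 CPM against 80.9 and 75.7 CPM. Cxcl16 had 27.3 and 25.3 CPM against 78.7 and 64.4 CPM, and Xcl1 and Ccl3, both under 0.3 CPM in the IgG libraries, had log2 fold changes of 4.15 ± 0.60 and 4.35 ± 0.53. In the other direction, 3 chemokine genes had both anti-PD-L1 libraries below both IgG libraries, Cxcl1, Cx3cl1 and Cxcl5, chosen after their values were seen, and Cxcl5, also in the NF-kB list, had the lowest log2 fold change of either (−3.57 ± 1.53). The chemokine count was lower without IgG replicate 1 and when either anti-PD-L1 library was left out. The chemokine median ranged from 1.11 to 2.01 with each library left out in turn.

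**Figure D2:**
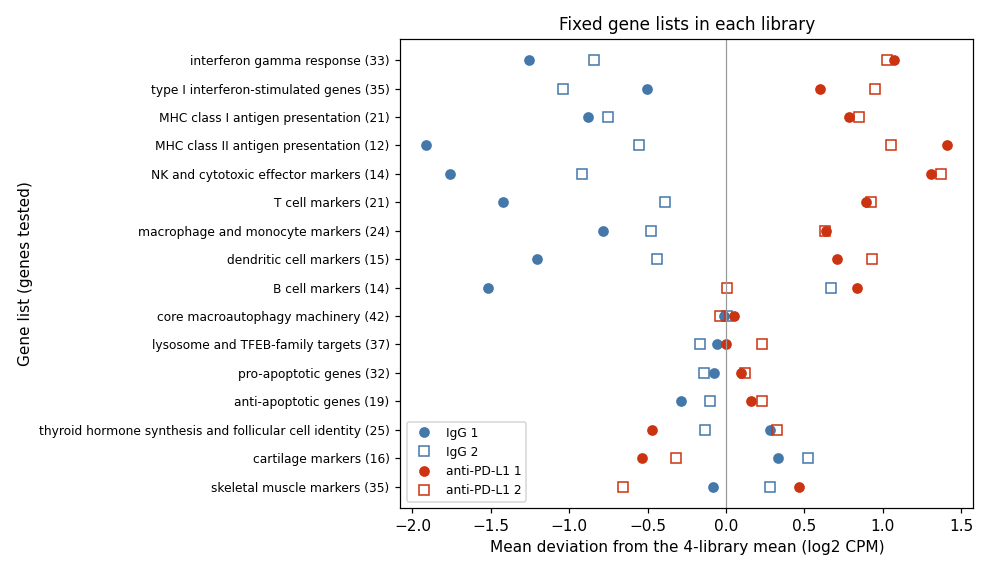
Each point is the mean deviation of a list's genes from their 4-library mean, in log2 CPM, in 1 library, with blue for IgG, red for anti-PD-L1, filled circles for replicate 1 and open squares for replicate 2, and the number of genes tested in brackets. The interferon gamma list lies at −1.26 and −0.84 in the IgG libraries and at 1.07 and 1.03 in the anti-PD-L1 libraries, whereas the B cell list lies at −1.52, 0.67, 0.84 and 0.0074.

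Macrophage and dendritic cell markers were also higher as lists. The macrophage list had 15 of 24 genes higher adjusted over the list alone and a median of 1.35 (camera adjusted p = 1.26e-25, and adjusted p = 0.224 with an estimated correlation). Fcgr1, the gene of the high-affinity IgG receptor, had 2.04 and 2.25 CPM against 10.9 and 10.5 CPM, and the complement genes C1qa, C1qb and C1qc, made by macrophages, had log2 fold changes of 2.16 ± 0.26, 2.29 ± 0.25 and 2.21 ± 0.25. The dendritic list had 8 of 15 genes higher adjusted over the list alone and a median of 1.499 (camera adjusted p = 2e-20, and adjusted p = 0.264 with an estimated correlation), with Clec9a, a marker of cross-presenting dendritic cells, at 1.00 and 1.18 CPM against 6.15 and 8.39 CPM. The dendritic count was lower when either anti-PD-L1 library was left out, while the median ranged from 1.25 to 1.90 with each library left out in turn. In the complement list 6 of 18 genes were higher adjusted over the list alone, among them C3ar1 and the C1q genes shared with the macrophage list, with a median of 0.80 (camera adjusted p = 8.21e-12, and adjusted p = 0.265 with an estimated correlation). Its median was 0.51 and its count 3 without IgG replicate 1, and its count was 10 without IgG replicate 2 and 4 without anti-PD-L1 replicate 2. B cell markers had a median of 0.44 and 0 of 14 genes past the threshold over the list alone (camera adjusted p = 0.0461, and adjusted p = 0.881 with an estimated correlation), and the call was lost without either replicate 1, with a median of −0.14 without IgG replicate 1 and 1.76 without IgG replicate 2. Ms4a1, the gene of CD20, had 3.35 CPM in IgG replicate 1, 17.1 CPM in IgG replicate 2, 22.5 CPM in anti-PD-L1 replicate 1 and 10.7 CPM in anti-PD-L1 replicate 2. The plasma cell list had a median of 0.31 and 0 of 8 genes past the threshold over the list alone (camera adjusted p = 0.0456, and adjusted p = 0.370 with an estimated correlation), with Jchain at 16.4 and 164 CPM against 1142 and 443 CPM. The call was lost without either anti-PD-L1 library.

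Autophagy and apoptosis are among the processes in the title of the series, which also names the response to cytokines. The 42 genes of the core autophagy list had log2 fold changes between −0.18 and 0.22, with 20 above 0 and 22 below (camera adjusted p = 0.957). The median and the test pointed lower and the mean (0.022) higher. Atg5 had a log2 fold change of 0.20 ± 0.16, Uvrag 0.21 ± 0.15, Atg4a 0.22 ± 0.21 and Vmp1 0.20 ± 0.19, none past the threshold over the list alone (adjusted p = 0.998 for each, edgeR). The list of mTORC1 and AMPK regulators had a median of −0.037 (camera adjusted p = 0.647), with Ddit4, an inhibitor of mTORC1, at 32.8 and 27.8 CPM against 50.5 and 51.2 CPM (edgeR adjusted p = 0.322, DESeq2 adjusted p = 0.0244). The lysosome list was called higher with a median of 0.16 (camera adjusted p = 0.00251, and adjusted p = 0.778 with an estimated correlation), with 0 of 37 genes past the threshold over the list alone. Macrophage markers, given above, were higher in the same comparison (median 1.35). Lipa, the gene of lysosomal acid lipase, had 26.1 and 23.3 CPM against 43.9 and 53.4 CPM, and Man2b1, Gusb and Npc2 had log2 fold changes of 0.72 ± 0.18, 0.65 ± 0.20 and 0.73 ± 0.25. The lysosome call was lost without IgG replicate 2 (median 0.14) and without anti-PD-L1 replicate 2 (median 0.060), and the median was 0.34 without anti-PD-L1 replicate 1.

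The pro-apoptotic list had a median of 0.25 and was called higher (camera adjusted p = 0.00818, and adjusted p = 0.264 with an estimated correlation), with 0 of 32 genes past the threshold over the list alone. Tnfsf10, the gene of the death ligand TRAIL and also interferon-inducible, had 23.8 and 21.1 CPM against 33.1 and 48.8 CPM, and Apaf1 had a log2 fold change of 0.67 ± 0.19. The call was lost without IgG replicate 2 (median 0.20) and without anti-PD-L1 replicate 2 (median 0.16). The anti-apoptotic list had a median of 0.045 (camera adjusted p = 0.0298, and adjusted p = 0.332 with an estimated correlation). Over the list alone 1 of 19 genes, Traf1, was higher, at 7.80 and 8.85 CPM against 18.54 and 20.96 CPM. Bcl2a1b and Bcl2a1d, near-identical genes expressed in leukocytes, had log2 fold changes of 2.38 ± 0.52 and 2.63 ± 0.86, and Birc3 had 0.43 ± 0.16. Without anti-PD-L1 replicate 2 the median was 0.0084 and the call was lost, and without anti-PD-L1 replicate 1 the median was 0.20.

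**Figure D3:**
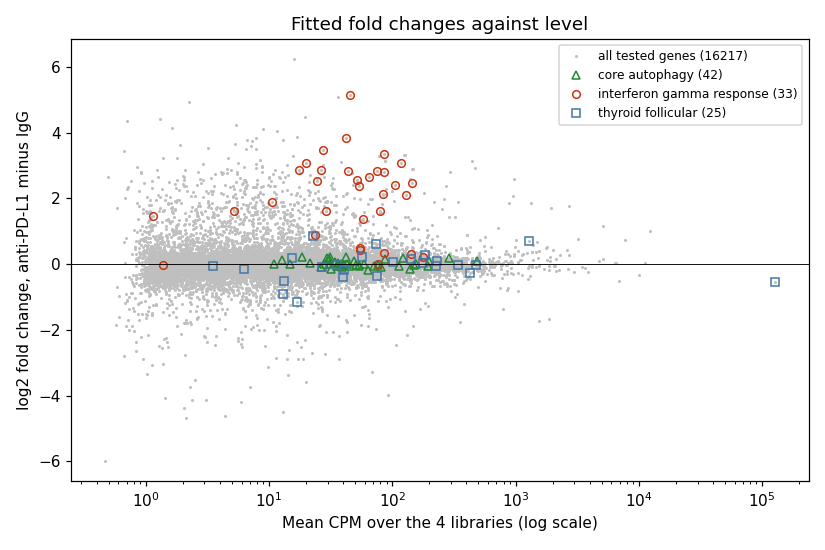
Fitted log2 fold change, anti-PD-L1 minus IgG, against mean CPM on a log axis for the 16217 tested genes in grey, with the interferon gamma list as red circles, the core autophagy list as green triangles and the thyroid follicular list as blue squares. The autophagy genes lie between −0.18 and 0.22, and the interferon gamma genes reach 5.16.

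Genes of thyroid hormone synthesis and follicular identity were not called as a list, with a median of −0.035 over 25 genes and 0 past the threshold over the list alone (camera adjusted p = 0.229). Tg had 152770 and 148532 CPM in the IgG libraries, 44667 CPM in anti-PD-L1 replicate 1 and 162488 CPM in anti-PD-L1 replicate 2. Duox1, an oxidase gene of hormone synthesis, had 33.1 and 13.4 CPM against 13.4 and 7.44 CPM, and Dio2, Duoxa1 and Clic3 had log2 fold changes of −0.50 ± 0.28, −0.91 ± 0.55 and −0.36 ± 0.23. The direction of the list depended on single libraries. Its median was 0.25 without anti-PD-L1 replicate 1 and −0.55 without anti-PD-L1 replicate 2, each with a camera call (adjusted p = 0.0165 and 3.16e-06), and it was called lower without IgG replicate 2, with a median of −0.16.

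Cartilage markers were lower as a list, with a median of −0.35 over 16 genes and 6 lower adjusted over the list alone (camera adjusted p = 1.34e-10, and adjusted p = 0.264 with an estimated correlation). Besides Acan and Hapln1, Comp had 13.7 and 22.4 CPM against 5.46 and 4.27 CPM and Chad 30.9 and 43.9 CPM against 16.7 and 13.7 CPM. Without IgG replicate 2 the count was 2 and without anti-PD-L1 replicate 1 it was 3. The cartilage median was between −0.73 and −0.39 with each library left out in turn. Cartilage is among the neighbouring tissues that a dissected thyroid could hold. A different amount of cartilage in the samples was not tested and cannot be told from an effect of the treatment. The list's genes did not fall alike, with log2 fold changes from −2.87 to 0.80. Col2a1, Col9a1 and Col11a1, chosen after their values were seen, had −0.25 ± 0.19, 0.089 ± 0.20 and −0.30 ± 0.22. The parafollicular C cell list was lower with a median of −0.30 (camera adjusted p = 0.0106, and adjusted p = 0.609 with an estimated correlation) and 0 of 16 genes past the threshold over the list alone, as with Pcsk1 at −0.59 ± 0.29. Its call was lost without either replicate 1, and its median ranged from −0.59 to −0.18 with each library left out in turn. The lists of the unfolded protein response (median 0.25), TNF and NF-kB targets (0.15) and thymocytes (0.25) were called higher with preset-correlation adjusted p of 0.0171, 0.0456 and 0.00955, and had adjusted p = 0.557, 0.383 and 0.326 with an estimated correlation. Over their lists alone 1, 1 and 0 genes passed, Edem1, an ER degradation factor, with 63.6 and 74.97 CPM against 181 and 191 CPM, and Traf1. T cell markers, with a median of 1.75, were higher in the same comparison as the thymocyte list, 3 of whose genes are in other lists and whose largest log2 fold changes were those of Cd4 (2.18 ± 0.51), Themis (1.75 ± 0.47) and Tcf7 (1.53 ± 0.39), also expressed by mature T cells. The call of the unfolded protein response list was lost without either replicate 2, that of the thymocyte list without either anti-PD-L1 library and that of the NF-kB list without any library but IgG replicate 2. With each library left out in turn the medians ranged from −0.026 to 0.38 for the unfolded protein response, from 0.083 to 0.24 for NF-kB and from 0.023 to 0.43 for thymocytes.

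The other 18 lists were not called. Median log2 fold changes were −0.39 for lymphatic and high endothelial venule markers, −0.075 for skeletal muscle, −0.094 for endothelium, −0.066 for glycolysis, 0.41 for red cells, −0.0014 for adipocytes, −0.35 for airway epithelium, 0.022 for oxidative phosphorylation and −0.19 for nerve. They were −0.067 for heat shock proteins, −0.12 for smooth muscle, 0.13 for fibroblasts, 0.11 for immediate early genes, −0.014 for proliferation, 0.098 for parathyroid, −0.16 for granulocytes, 0.075 for ribosomal proteins and −0.012 for antioxidant genes. Among named genes of these lists DESeq2 called Myh8 and Slc16a3, with log2 fold changes of −1.77 ± 0.32 and −0.72 ± 0.15, and Thy1, Csf3r and Cldn5, with 0.97 ± 0.17, 1.17 ± 0.29 and −0.66 ± 0.16, and edgeR called none. The median, mean and test differed in sign for oxidative phosphorylation and proliferation as well as autophagy.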

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

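The count of 0 genes in each direction was the same under every scaling, filter, tool and left-out library tried, apart from DESeq2, which called 475 higher and 53 lower, and an adjusted p under 0.10, which gave 15 higher. With DESeq2, leaving out a library, added after seeing the data, gave 197 higher and 30 lower without IgG replicate 1, 491 and 24 without IgG replicate 2, 483 and 656 without anti-PD-L1 replicate 1 and 430 and 355 without anti-PD-L1 replicate 2. In every fit with a library left out, the lone sample was assumed to vary like the other group. DESeq2 with the replicate number as a block, also added after seeing the data, gave 418 higher and 150 lower. The block in edgeR left 0 genes and gave 15 lists higher and 1 lower, with the anti-apoptotic list at 0.052 (adjusted p = 0.0552) and the calls of the unfolded protein response, NF-kB, plasma cell and C cell lists also lost. Plain library-size scaling gave 16 lists higher, the NF-kB, B cell and plasma cell calls being lost, and 2 lower. Same-numbered libraries deviated from their group means with a correlation of 0.0998, and the labels give no pairing. Blocks with the numbers crossed were fitted before this correlation was computed and are not used. With an estimated correlation 0 lists were higher and 0 lower, with the pro-apoptotic median of 0.25 at adjusted p = 0.264 and the anti-apoptotic median of 0.045 at adjusted p = 0.332. fry called 2 higher and 0 lower, with both apoptosis lists at adjusted p = 0.139, and its direction was opposite to camera's for autophagy (median −0.00095) and antioxidant genes (median −0.012). Leaving out neighbouring-tissue genes gave 0 lists lower, since it removes the genes of both. The median log2 fold change of all genes was between −0.0146 and 0.0203 under the edgeR settings.

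With each library left out in turn, 16 to 19 lists were higher and 4 to 7 lower, and medians ranged from 0.16 to 0.31 for the pro-apoptotic list, 0.0084 to 0.20 for the anti-apoptotic list, −0.037 to 0.044 for autophagy and −0.55 to 0.25 for thyroid follicular genes. The test or median turned direction at least once for B cells (−0.14 to 1.76), antioxidant genes (−0.057 to 0.056), ribosomal proteins (−0.33 to 0.40), proliferation (−0.38 to 0.36), granulocytes (−0.41 to 0.18), parathyroid (−0.25 to 0.91), airway (−0.95 to 1.67), lymphatic markers (−0.43 to 0.18), immediate early genes (−0.17 to 0.17), adipocytes (−0.67 to 0.50), nerve (−0.49 to 0.024), endothelium (−0.36 to 0.051), glycolysis (−0.33 to −0.021), oxidative phosphorylation (−0.45 to 0.33), heat shock proteins (−0.23 to −0.015), the unfolded protein response (−0.026 to 0.38), mTORC1 and AMPK regulators (−0.080 to 0.032), muscle (−0.92 to 0.33) and fibroblasts (−0.16 to 0.41). Named genes were mostly picked for a small p or for groups that did not overlap, which favours a kept direction. Of 133 named genes 125 kept their direction in each of 14 settings that gave them a value. Genes of neighbouring tissues have none where those genes were left out, and the DESeq2 fits with a library left out or with the block were read for counts of calls alone. The others were Blk (−0.14 to 1.56), Ms4a1 (−0.066 to 2.31), Lcn2 (−3.81 to 0.12), Atg4a (−0.0068 to 0.41), Bpifb1 (−1.91 to 2.70), Fau (−0.16 to 0.57), Rps27 (−0.54 to 0.86) and Tg (−1.77 to 0.11). The cause was not tested for these lists and genes, apart from Tg and the follicular genes, for which explanations are weighed below. Genes below a count of 100 in every library had been removed before deposit, so nothing can be said of them. Genes under 100 counts in both IgG libraries, such as Prf1 and Ccl3, were kept only through an anti-PD-L1 library. This favours higher values in lists of low genes. At the depth of these libraries 3 counts correspond to 0.0377 to 0.0397 CPM.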

Other observations

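All genes, lists and tests in this part were chosen after results were seen, and the clock lists were written after clock values were seen. The tests of the follicular share and of lymphoid tissue were redefined after their values were seen. Psmb8, Psmb9 and Psmb10, the immunoproteasome subunits, had a median log2 fold change of 2.12, and all 3 were higher adjusted over that list alone. Psmb5, Psmb6 and Psmb7, the subunits they replace, had a median of 0.062, with 0 past the threshold over that list alone. The 2 sets were not tested against each other. Regulators of antigen presentation had higher values in both anti-PD-L1 libraries, with Nlrc5, the MHC class I transactivator, at 4.002 and 5.069 CPM against 15.9 and 17.3 CPM and Ciita, the class II transactivator, at 2.80 and 11.8 CPM against 39.8 and 43.7 CPM. Ifng itself had 1.15 and 1.35 CPM against 2.84 and 2.95 CPM. Cxcl9 had 0.738 and 4.19 CPM against 87.3 and 88.3 CPM, and Cxcr3, the receptor of CXCL9 and CXCL10, had 0.413 and 1.54 CPM against 15.95 and 17.78 CPM. Ido1, another gene of the interferon gamma list, had 1.30 and 1.497 CPM against 1.44 and 1.28 CPM.

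Among Fc receptor genes, Fcgr4 had 1.25 and 0.801 CPM in the IgG libraries and 19.2 and 10.0 CPM in the anti-PD-L1 libraries, and Fcgr2b, the inhibitory receptor, had 3.39 and 5.94 CPM against 11.35 and 6.80 CPM. Gsdmd, the gene of the pore-forming protein gasdermin D, had 9.72 and 10.0 CPM against 17.6 and 21.1 CPM, while Casp1 had a log2 fold change of 0.28 ± 0.20. Within cartilage genes, Col10a1 had 113 and 134 CPM against 6.78 and 18.6 CPM and Matn1 13.26 and 18.25 CPM against 3.85 and 1.75 CPM, whereas Col2a1 and Col9a1 had log2 fold changes of −0.25 ± 0.19 and 0.089 ± 0.20. Over all genes edgeR called none of the genes in these 2 paragraphs, while DESeq2 called the 3 immunoproteasome genes, Nlrc5, Ciita, Ifng, Cxcl9, Cxcr3, Fcgr4, Gsdmd, Col10a1 and Matn1.

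Higher values of interferon and antigen presentation genes in both anti-PD-L1 libraries are the pattern that the treatment groups would give if blockade raised them. A male animal in the group did not account for it, since the interferon gamma median was 2.24 without anti-PD-L1 replicate 1. Lymphoid tissue with B cells carried over stays open, since 2 of 14 B cell genes had both anti-PD-L1 libraries above both IgG libraries but the B cell median was 1.76 without IgG replicate 2. With 3 ways to split 4 libraries into equal groups, chance could not be told from an effect. The treatment split was 1 of 3 to reach its 528 DESeq2 calls, the highest other split giving 99, and 1 of 3 to reach 21 lists with the preset correlation, the highest other split giving 20.

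Anti-PD-L1 replicate 1 stood apart. It had 3.46-fold less Tg than the mean of the other 3 libraries on the log scale, and 21 of the 24 other follicular genes were lower in it, with a median of −0.56. A smaller share of follicular cells, with all other cell types kept in proportion, would raise the lists of those types alike. Instead, 5 of 12 lists of other non-immune cell types were also lower in this library (75th percentile below 0), while 2, muscle and airway, were higher. The test cannot decide on a smaller follicular share that comes with more of some other tissue, which could both lower and raise lists. A swap of labels with an IgG library was not supported, as 31 of 33 interferon gamma genes had both anti-PD-L1 libraries above both IgG libraries. Whether Tg goes with a male animal (Ddx3y 62.6 CPM) cannot be told, as no other library had Y-linked genes at such levels, and no biological explanation was tested.

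Clock genes of opposite phase had values in opposite directions. Dbp had 5.43 and 13.3 CPM in the IgG libraries and 66.5 and 47.3 CPM in the anti-PD-L1 libraries, and Arntl 35.96 and 31.9 CPM against 15.9 and 18.6 CPM. The median log2 fold change of 11 genes of the Dbp and Per phase was 1.24 above that of 4 genes of the Arntl phase, with 0 genes past the threshold over either list alone, which describes genes picked for the pattern, Dbp among them, and is no independent test of it. A different hour of harvest for the groups, or an effect of the treatment on the clock, would each give this, and the labels give no harvest time, so the cause stays open. A different share of skeletal muscle was not supported, as at most 4 of 35 muscle genes had the groups apart in 1 direction.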
